A study of Mus musculus with 2 samples.

How the data were processed

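Medulloblastoma cells from mice carrying CAG-CreER and Rosa26-SmoM2 were dissociated, crosslinked and immunoprecipitated with the J1 antibody, per the labels' protocols, and an input library was made without antibody. Libraries were made with a NEBNext ChIP-seq kit and sequenced on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.7, Picard 1.127 and SICER 1.1, and the builds mm9 and mm10, without saying which step used which. The SICER window, gap and thresholds, and whether the input served as the control, are not given in the sources used here. How many animals or tumours went into the library is likewise not given in the sources used here.

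The deposited list for the ChIP library holds 5727 islands, each with a chromosome, a start, an end and a whole number. The authors' whole numbers were taken as the count of reads in each island, from their values: no column names are given, the minimum rose with island width (33 at 1000 bp, 48 at 2000 bp, 61 at 3000 bp), and the Spearman correlation with width was 0.917 across islands, which are not independent replicates. The count is the authors' own value and was used only to describe, rank and filter islands within this list. It is not scaled for depth, and a wide island has more reads because it is wider, so reads per 200 bp were computed as a density (median 6.27). Density does not remove the effect of width, since it was higher in narrow islands. The list holds only regions that passed the caller, so a gene without an island is not shown to lack Brg1.

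The build of the deposited coordinates was settled from the data. The annotation given was RefSeq on GRCm38.p6, which matches mm10. With the coordinates as deposited 1861 islands lay within 1 kb of a protein-coding gene end, and with the list moved by 10 to 200 kb between 501 and 575 did. Widths were whole multiples of 200 bp in 5724 of 5727 islands, while starts fell on 3 to 22 different positions within 200 bp per chromosome. Whether the islands were called on mm9 and then moved to mm10, and whether any were lost by it, was not settled. Coordinates are given 1-based on mm10.

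The annotation gave gene extents without strand or exons, and no genome sequence was used. The planned tests were therefore changed in these ways. Both ends of a gene stood in for its transcription start, exons and introns were merged into the gene interior, the span between the outermost genes or islands of a chromosome stood in for its sequenced length, and random gene lists were matched on length alone. The planned tests of 20 motifs and of GC and CpG content were not run.

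The share of islands within 1 kb of a gene end, the position classes by midpoint and the spacing were compared with 1000 random placements of the same islands on the same chromosomes. Island numbers per chromosome were compared with its length by exact binomial tests. Each of 19 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, on the number with an island within 5 kb of an end. Beside it, each list was set against 10000 length-matched random lists (20 length bins) and 10000 rotations of gene order, which keep neighbouring genes together. Medians of gene-end and distal islands were compared with 100000 permutations. P-values were adjusted by Benjamini-Hochberg over the 19 lists, the 20 chromosomes or the position classes, with a threshold of 0.05. Shares carry Wilson 95% intervals and reads exact Poisson 95% intervals. Beside a count of 0, the share that 3 counts would make is given as the limit. These treat reads and genes as independent, which neighbouring genes that share an island are not.

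The lists, the tests and their alternatives were fixed before the data were examined, apart from those named as added. The lists covered the Hedgehog, Wnt, and TGF-beta and BMP pathways, granule neuron progenitors and granule neuron differentiation, stem and glial progenitors, the cell cycle, BAF and chromatin regulators, neuronal bHLH and homeodomain regulators, markers of oligodendrocytes, astrocytes and Bergmann glia, microglia and macrophages, and endothelial and mural cells, liver and muscle genes, housekeeping, ribosomal protein, histone, olfactory receptor and Hox genes. All fixed symbols matched the annotation, some through synonyms, except 1 of 42 stem and glial names and 1 of 40 housekeeping names. Genes named in the text, apart from those said to be chosen after their values were seen, are the 10 islands with the most reads near gene ends, up to 4 members per list by reads, 18 genes fixed in advance, the 5 genes with the most islands and the 3 widest islands. Some genes that this rule takes are not reported here.

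Alternatives were the islands with higher counts, islands of at least 1 kb, other windows, midpoints, all annotated genes, the nearest gene only, shifts of 50 to 500 kb as random placement, other distances, and gene number as the chromosome denominator. Added after seeing the data were the removal of 31 islands with over 2 times the median density, of chromosome X and of genes on more than 1 list, the use of distal islands, and comparisons of gene-end and distal islands within width. The list code was run on simulated islands scattered at random, with 200 laid across the lower-coordinate end of planted genes. All 200 planted genes among 21631 were recovered, which their placement fixed in advance, so this checks the code and not its power. Of 1000 random lists 4.3% fell under 0.05, and 300 genes gave 0 differences from a direct count. The 4.3% does not cover clustered islands or lists of neighbouring genes, which the real data hold. Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.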

Results

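Binding of Brg1, the ATPase encoded by Smarca4 that drives the BAF (SWI/SNF) chromatin remodelling complex, was profiled by ChIP-seq in mouse medulloblastoma. Such tumours arise spontaneously in animals carrying CAG-CreER and Rosa26-SmoM2, and model the Shh type of this cerebellar cancer. SmoM2 is an activated form of the Hedgehog signal transducer Smoothened. The labels describe the J1 antibody as directed against Brg1 and its paralogue Brm, encoded by Smarca2, so the islands below can hold either ATPase. There was 1 ChIP library and 1 input library, and the input is not analysed here. With 1 ChIP library there was no error between animals, and every test below compares this island list with random placement, with gene lists or with other islands, not conditions. The ChIP library was represented by 5727 enriched regions (islands) with a median width of 2200 bp (interquartile range 1600 to 3000) and a median of 68 reads (interquartile range 56 to 86). The islands covered 14.2 Mb and held 472238 reads; the depth of the whole library is unknown. Intervals on reads and shares cover counting error only.

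Brg1 islands were concentrated at gene ends. Of the 5727 islands, 1861 (32.5%, Wilson 95% interval 31.3 to 33.7) lay within 1 kb of an end of a protein-coding gene, against 6.52% ± 0.331 (SD over 1000 random placements). This was a 4.99-fold excess (two-sided permutation p = 0.001, the smallest the placements can give). The fold was 7.86 when the island midpoint had to lie within 1 kb and 2.68 with a window of 5 kb. Against islands shifted by 50 to 500 kb it was 3.54. By midpoint, 1415 islands (24.7%) lay at a gene end, 2540 (44.4%) further inside a gene, 363 (6.34%) outside but within 10 kb of a gene, and 1409 (24.6%) over 10 kb from any gene. The last class was under-represented, at 0.497 times random placement, and the gene-end class over-represented, at 7.83 times (adjusted permutation p = 0.001 for each). Against shifted islands these ratios were smaller effects, at 0.677 and 5.48. The share inside genes was 1.14 times that of random placement but 0.909 times that of islands shifted by 50 to 500 kb, so its direction depended on the comparison.

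**Figure D1:**
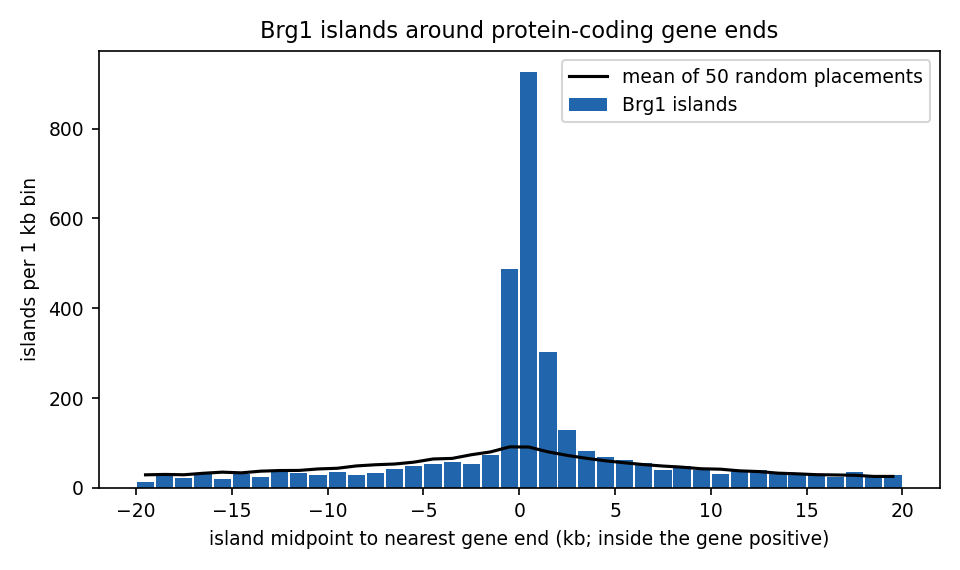
Number of Brg1 islands (bars) per 1 kb bin of distance from the island midpoint to the nearest protein-coding gene end, in kb, with positions inside the gene positive; the line is the mean of 50 random placements. The 2 bins next to the gene end hold 488 and 927 islands against 91.2 and 90.9 in random placements.

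Among 9975 protein-coding genes longer than 20 kb, 627 had an island within 1 kb of the lower-coordinate end and 644 within 1 kb of the higher-coordinate end. Both ends had one in 28 genes, against 40.5 if the ends were independent (odds ratio 0.663, two-sided exact Fisher p = 0.0356, in a test added after seeing the data). Of the 1243 genes with an island at either end, 97.7% had it at 1 end only, and 96.7% would with independent ends. Strand was not used here, so which of the ends is the transcription start is not stated.

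Chromosome X carried few Brg1 islands. It held 23, against 374 expected from its length (0.0615 of expectation, adjusted exact binomial p = 1.1e-129) and 256 expected from its protein-coding genes (0.0899 of expectation, adjusted exact binomial p = 2.4e-79). The 19 autosomes held between 1.73 and 3.54 islands per Mb, and X held 0.135. By length, 5 chromosomes (2, 4, 5, 9 and 11) had more islands than expected and 5 (1, 3, 6, 16 and X) had fewer, at adjusted exact binomial p under the threshold. With gene number as the denominator 9 chromosomes passed, but only chromosomes 4 and X passed in the same direction under both, and chromosome 3 changed direction. Chromosome 11, with 432 islands and 1.62 times the expectation by length, was at 1.01 times the expectation by genes.

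**Figure D2:**
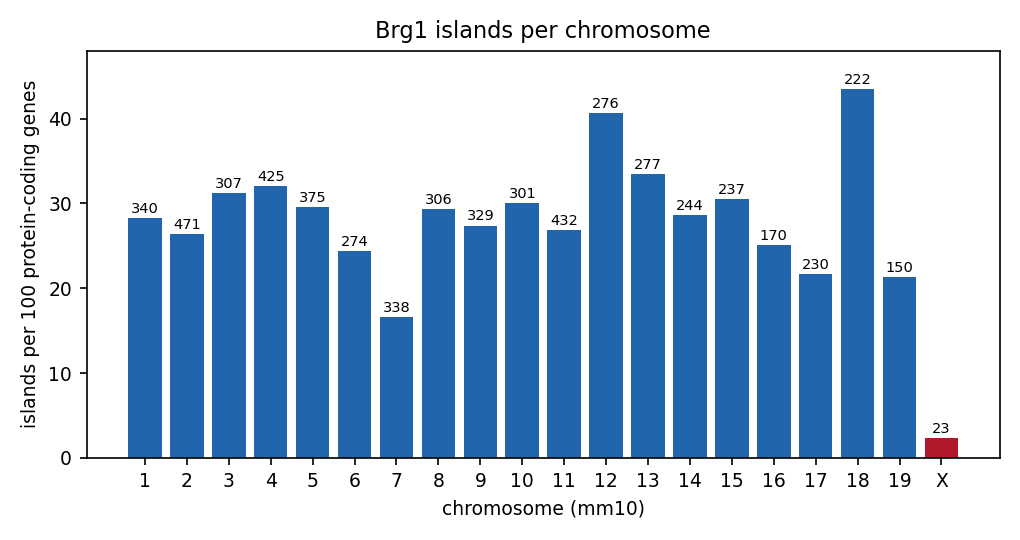
Brg1 islands per 100 protein-coding genes (vertical axis) on each mouse chromosome (horizontal axis, mm10), with the number of islands above each bar. Chromosome X has 2.38 islands per 100 genes, and the autosomes lie between 16.7 and 43.4.

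Of 21631 protein-coding genes, 2823 (13.1%) had an island within 5 kb of an end. This count fell to 1558 with the 2938 islands at or above the median read count, and to 825 with the 1464 islands of highest count. Of 19 gene lists fixed before the data were examined, 7 had islands more often than the other genes, 2 less often, and 10 did not pass the threshold. Each of the 7 lay at percentile 99.855 or higher among random lists matched on gene length.

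Genes of granule neuron progenitors, the cells from which Shh-type medulloblastoma arises, had the highest share within 5 kb of a gene end. An island lay there in 27 of 42 (64.3%, Wilson 95% interval 49.2 to 77.0) against 13.0% of the other genes (odds ratio 12.1, adjusted exact Fisher p = 1.5e-13). The members with the most reads were Nfia, a nuclear factor I gene, with 231 reads, the homeobox genes Barhl1 with 201 and Meis1 with 192, and Zic5, a zinc-finger gene, with 156. The islands of Meis1 and Zic5 lay outside the gene, 1031 and 4982 bp from its lower-coordinate end. Atoh1, the bHLH factor that specifies the granule lineage, had an island of 89 reads across its lower-coordinate end (chromosome 6, 64727007 to 64730406, mm10). Zic1 had one of 85 reads outside the gene, 1195 bp from its higher-coordinate end, which was also the island assigned to Zic4. No island lay near Meis2, En1, Lhx9, Pax3 or Hes1, named here after their values were seen. Of the 42 members, 10 also stood on other lists. The rank depended on the window: within 1 kb, 19 of the 42 had an island (odds ratio 7.66) against 18 of 39 housekeeping genes (odds ratio 7.94). The odds ratio was 4.39 with islands over 5 kb from any gene end only, where differentiation genes had 7.84.

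Hedgehog pathway genes also had islands more often: 16 of 44 (36.4%, Wilson 95% interval 23.8 to 51.1; odds ratio 3.82, adjusted exact Fisher p = 2.1e-04). Ptch1, the Hedgehog receptor and a target of the pathway, contained 5 islands. The one with the most reads lay inside the gene, 2768 bp from its higher-coordinate end (chromosome 13, 63564893 to 63570692, 159 reads, exact Poisson 95% interval 135 to 186). Gli1, the transcription factor that serves as a readout of the pathway, had an island of 131 reads (110 to 155) across its higher-coordinate end (chromosome 10, 127338145 to 127342344). Ccnd1 (cyclin D1) had one of 131 reads (chromosome 7, 144939696 to 144944295), Mycn one of 94 reads (chromosome 12, 12941195 to 12943994), Sufu one of 81 and Ccnd2 one of 65. Inside the gene, over 5 kb from its ends, Sufu also had islands of 120 and 59 reads and Ccnd2 one of 66. Spop, a ubiquitin ligase adaptor, had an island of 153 reads. Gli2 had none near an end but 2 inside the gene, of 93 and 73 reads. Gli3, Smo and Hhip had no island within 5 kb of the gene, with the nearest 1963, 285 and 324 kb away. Without islands of unusually high read density, 15 of the 44 members had one (odds ratio 3.47, adjusted exact Fisher p = 7.5e-04). Of the members, 8 stood on other lists, and without those the odds ratio was 2.57 (adjusted exact Fisher p = 0.0496).

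**Figure D3:**
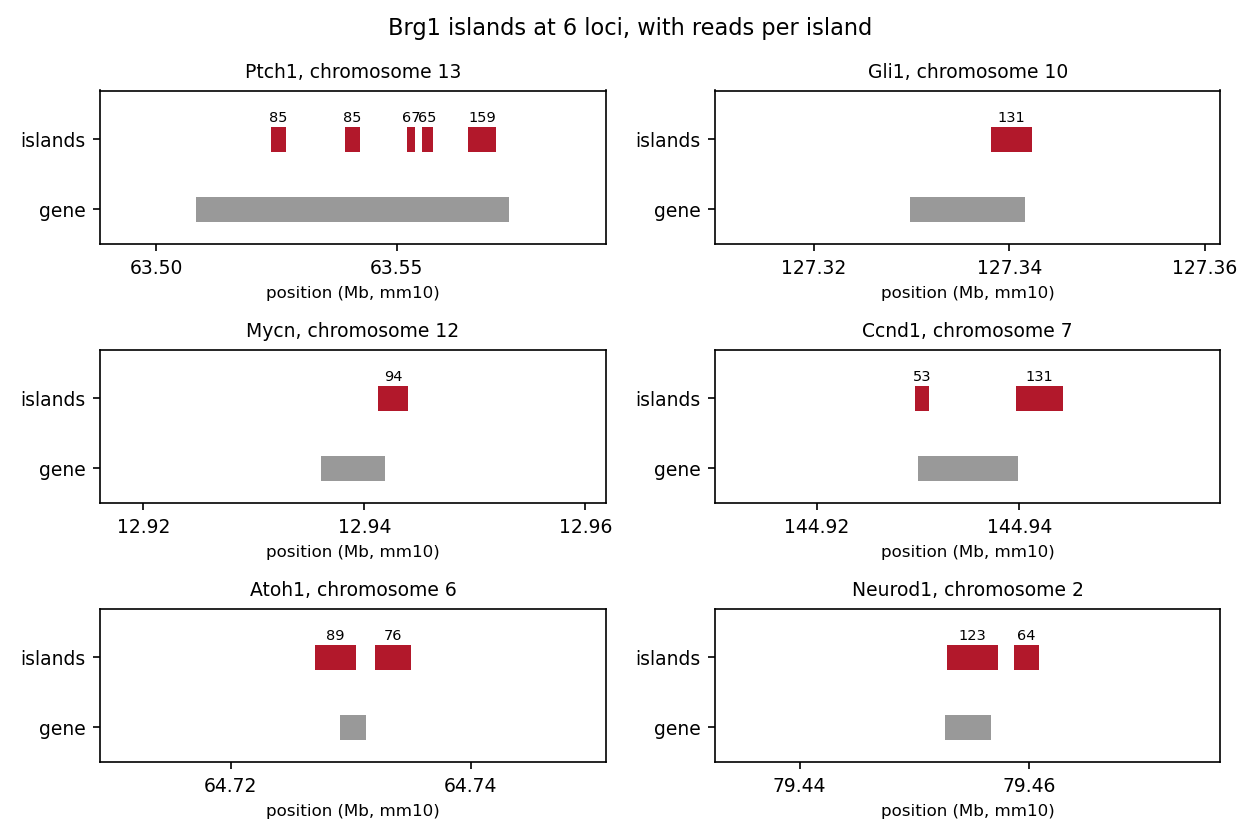
Brg1 islands (red, with reads per island) and gene extents (grey) at Ptch1, Gli1, Mycn, Ccnd1, Atoh1 and Neurod1, against position in Mb (mm10), each panel extending 20 kb beyond the gene. Ptch1 carries 5 islands of 65 to 159 reads.

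Genes of granule neuron differentiation had islands in 17 of 42 (40.5%, Wilson 95% interval 27.04 to 55.5; odds ratio 4.55, adjusted exact Fisher p = 2.8e-05). Sema6a, a semaphorin gene, had an island of 187 reads, the bHLH factor Neurod1 one of 123 (chromosome 2, 79452844 to 79457243), Stmn2 one of 100 and the synaptic adhesion gene Nlgn1 one of 98. With islands anywhere in the gene or 5 kb around it, 27 of the 42 were counted (odds ratio 8.91).

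BAF subunits and other chromatin regulators had islands in 27 of 54 (50%, Wilson 95% interval 37.1 to 62.9; odds ratio 6.72, adjusted exact Fisher p = 3.0e-10). Among them were the genes of both ATPases, Smarca4 with 54 reads (chromosome 9, 21615357 to 21617156) and Smarca2 with 93 (chromosome 19, 26604711 to 26608110). The highest counts were at Kdm6b, a histone demethylase, with 134 reads, the remodeller Chd7 with 132, the BAF subunit Arid2 with 129 and Bcl11a with 126.

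Canonical histone genes had islands in 32 of 68 (47.1%, odds ratio 5.98, adjusted exact Fisher p = 5.6e-11). These rested on 15 distinct islands, since clustered genes shared them: a single island of 202 reads on chromosome 13 (21779332 to 21787331) served H1f5, H2ac22, H2bc22 and H3c11. The two-sided permutation p over rotations of gene order, which keeps neighbouring genes together, was 0.0002. The symbol pattern behind this list also took in H13, which is not a histone gene.

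Housekeeping genes, a control for generally active genes, had islands in 18 of 39 (46.2%, odds ratio 5.74, adjusted exact Fisher p = 1.8e-06), led by Eef2 with 244 reads, Actb with 217, Srsf3 with 153 and Tubb5 with 137. Cell cycle genes had them in 16 of 56 (28.6%, odds ratio 2.67, adjusted exact Fisher p = 0.0048), with 131 reads at Ccnd1, 114 at Trp53, 94 at Mycn and 86 near Aurkb. The island near Aurkb lay outside the gene, 3126 bp from its lower-coordinate end. The cell cycle call was lost without the 5 genes held by other lists (odds ratio 2.05, adjusted exact Fisher p = 0.0749). It was lost too with the 1464 islands of highest count (odds ratio 1.94). With islands over 5 kb from any gene end, the odds ratios of the cell cycle, chromatin, histone and housekeeping lists were 1.57, 1.84, 1.67 and 1.66, none past the threshold.

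Compared directly with housekeeping genes, no list passed as having islands near gene ends more often, and 10 lists had them less often. Among these were Wnt, TGF-beta and BMP, and ribosomal protein genes (adjusted exact Fisher p = 0.0229, 0.0109 and 2.8e-04). Genes on both lists counted as housekeeping only, which left 83 ribosomal protein genes. Against housekeeping genes the granule neuron progenitor list had an odds ratio of 2.10 (adjusted exact Fisher p = 0.155). The chromatin list had 1.17 (adjusted exact Fisher p = 0.883) and the Hedgehog list 0.667 (adjusted exact Fisher p = 0.458).

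The lists with fewer islands were those of gene families clustered along chromosomes. Only 2 of 1110 olfactory receptor genes had an island, Olfr750 and Olfr1344 (odds ratio 0.0113, adjusted exact Fisher p = 2.0e-64), each outside the gene. None of 39 Hox cluster genes did, where 3 counts would be a share of 7.69% and the Wilson 95% upper bound is 8.97% (adjusted exact Fisher p = 0.0155). Over rotations of gene order, which allow for the clustering of Hox genes, the two-sided permutation p was 0.083.

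Among the lists that did not pass, stem and glial progenitor genes had islands in 9 of 41 (22.0%, odds ratio 1.88, adjusted exact Fisher p = 0.161). This call depended on how islands were assigned to genes, since the list passed with 4 of 12 alternatives, at odds ratios of 2.76 (10 kb window), 3.15 (gene body), 3.48 (nearest gene end) and 4.13 (distal islands, added after seeing the data). The members with the most reads were Olig1 with 102, Sox1 with 82, Cspg4 with 81 and Hey1 with 68; Sox2 had an island of 56 reads and the island nearest to Olig2 lay 32.0 kb away. Wnt pathway genes had islands in 11 of 53 (odds ratio 1.75), led by Axin2 with 138 reads, and regulators of other neuron types in 9 of 46 (1.62), led by Pou3f3 with 163. The odds ratios were 1.11 for TGF-beta and BMP pathway genes (6 of 42; Id2, 103 reads) and 0.888 for ribosomal protein genes (10 of 85; Rpl4, 130 reads). The island of Id2 lay outside the gene, 2444 bp from its higher-coordinate end. Markers of other cell types that a tumour can hold had islands in 4 of 20 astrocyte and Bergmann glia genes (odds ratio 1.67), 2 of 20 oligodendrocyte genes (0.740), 2 of 20 microglia and macrophage genes (0.740) and 2 of 22 endothelial and mural genes (0.666). Liver and muscle genes had 1 of 36, Acta1 (0.190).

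**Figure D4:**
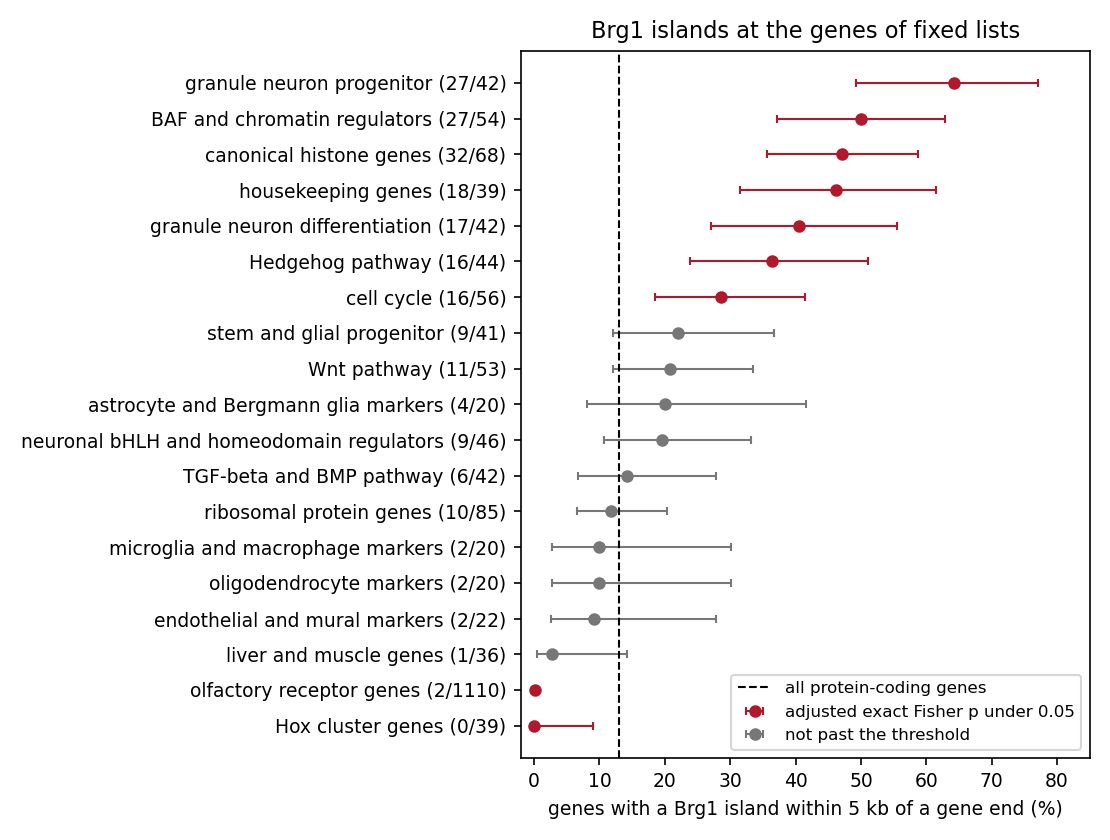
Share of each fixed gene list with a Brg1 island within 5 kb of a gene end (horizontal axis, %), with members counted in brackets; points are shares, bars Wilson 95% intervals, red points lists past the adjusted exact Fisher threshold and the dashed line all protein-coding genes (13.1%). At this window granule neuron progenitor genes lie highest, at 64.3%, and olfactory receptor and Hox genes lowest, at 0.18% and 0%.

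Some genes carried many islands. Gse1 had 22 between 5 kb before and 5 kb after the gene, Nfia 18, Lrba 15, and Cacna2d1, a calcium channel subunit gene, and Tcf4, a bHLH factor gene, 10 each. In 100 random placements the highest number on any gene was 14, and the median of the highest was 9. The 10 islands of Cacna2d1 and of Tcf4 lay within that range. Random placement does not keep neighbouring islands together, so these numbers do not allow for the spacing of islands. The 18 islands of Nfia corresponded to 3.27 islands per 100 kb, against 0.219 overall. Nfia was named for its number of islands, so a rate above that of the whole list follows from the choice.

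Several of the 10 islands with the most reads near gene ends had unusually high read density. Among these were the islands at Sfi1 (20753 reads over 78400 bp, also assigned to Gm51877 and Eif4enif1), Sp140 (1519), Mid1 (1367), A530032D15Rik (811) and Apool (286). Others had ordinary density: Mab21l1 with 354 reads over 11600 bp, Setd1b and Rhof with 340, Slc29a1 and Mymx with 275, and Kmt2e with 254. The 3 widest islands were those at Sfi1 (chromosome 11, 3121798 to 3200197) and Mid1 (20000 bp on chromosome X) and one of 24200 bp on chromosome 9 (3014201 to 3038400), which overlapped no gene and lay 297 kb from Alkbh8.

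Gene-end islands held slightly more reads than distal ones, a difference that the definition of the classes favours. An island counted as gene-end if any part of it lay within 1 kb, which wide islands, with more reads, meet more easily. In random placements 6.52% of all islands met it, and 8.19% of the 1464 islands of highest count. The median was 71 reads in the 1861 gene-end islands and 67 in the 3367 islands over 5 kb from any gene end (two-sided permutation p = 0.00016). The median density, which fell with width (Spearman -0.648 across islands, which are not independent), was 6.11 against 6.36 reads per 200 bp (two-sided permutation p = 1e-05, the smallest the resamples can give). Median widths of 2400 and 2200 bp did not pass the threshold (two-sided permutation p = 0.0585). Among islands of the same width, the median count relative to that width was 1 in both classes, a difference of 0 (two-sided permutation p = 1 within width). The mean percentile of reads within width, computed because whole-number counts tie that median and after its value was seen, was 48.8 at gene ends and 51.03 at distal islands (two-sided permutation p = 0.00833 within width).

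Islands also lay near each other. Another island was found within 20 kb of 29.96% of islands, against 10.2% ± 0.553 in random placements (SD over 1000), a 2.94-fold excess (two-sided permutation p = 0.001). Against islands shifted by 50 to 500 kb the excess was 1.59-fold (two-sided permutation p = 0.001).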

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

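Distal islands, comparison within width, and the removal of high-density islands, of chromosome X and of genes on more than 1 list, were chosen after seeing the data. Of 267 alternative values with a test, 235 kept their direction and their side of the threshold; of 12 plain counts, 10 stayed within 1.5 times the reported count. A count hides which units pass: 10 chromosomes passed by length and 9 by gene number, but 3 both ways, 1 of these in opposite directions. Both of these counts rest on expectations that include chromosome X, whose few islands raise the autosomal ratios. The Hedgehog, granule neuron progenitor, granule neuron differentiation and olfactory receptor lists kept both under all 12 alternatives each, with odds ratios from 2.42 to 5.65, 4.39 to 17.5, 4.41 to 8.91 and 0 to 0.0441. The share of islands inside genes, 44.4%, was above random placement but below the 48.8% of shifted islands. The density difference between gene-end and distal islands was 0 as a median ratio within width, no longer past the threshold, but lower at gene ends by mean percentile within width. Genes with an island numbered 1558 with islands at or above the median count and 825 with the 1464 of highest count, since fewer islands were used.

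The cause of the following changes was not tested. With islands at or above the median count, the odds ratio was 2.72 for neuronal bHLH and homeodomain genes (now past the threshold), 0.678 for astrocyte, 1.43 for microglia and 0 for Hox genes (no longer past it). With the islands of highest count it was 0.630 for stem and glial, 1.94 for cell cycle (no longer past the threshold), 0.989 for Wnt, 0.615 for TGF-beta and BMP, 1.33 for microglia and 0 for Hox genes (no longer past it). With islands of at least 1 kb it was 0.914 for TGF-beta and BMP genes. With a 1 kb window it was 1.02 for oligodendrocyte and 0 for Hox genes (no longer past the threshold). With a 10 kb window it was 2.76 for stem and glial genes (now past it), 0.886 for TGF-beta and BMP and 1.05 for ribosomal genes. With gene bodies and with the nearest gene end, stem and glial genes passed at 3.15 and 3.48, and endothelial genes turned to 1.09 and 1.09. With distal islands stem and glial genes passed at 4.13, while cell cycle (1.57), chromatin (1.84), housekeeping (1.66), histone (1.67) and Hox genes (0.169) no longer did, and oligodendrocyte and endothelial genes turned to 1.14 and 1.43. Without genes on another list, cell cycle genes no longer passed (2.05) and TGF-beta and BMP genes turned to 0.784. The alternatives for motifs and GC content were not run. No paired analysis was possible because there was 1 ChIP library. The lowest island count was 27 reads, so regions with fewer reads are not covered.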

Other observations

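The comparisons of gene types, of distal islands with gene lists, and of gene-name families, and the housekeeping comparison near gene ends, were chosen after the results were seen. Gene number as the denominator for chromosome X was fixed in advance, but the bound used below to weigh it was set after its value was seen. Transfer RNA genes had the highest share with Brg1 islands of the 10 gene types tested, with differences between types not tested. An island lay within 1 kb of 97 of 408 (23.8%, Wilson 95% interval 19.9 to 28.1). The 48 islands concerned were 8.73 times the number in lists shifted by 50 to 500 kb (adjusted permutation p = 0.002). Of the 300 tRNA genes over 5 kb from any protein-coding gene end, 56 (18.7%) had an island, through 25 islands against 3.69 in shifted lists (permutation p = 0.001). Islands lay within 1 kb of 5.86% of lncRNA genes (2.19 times the islands of shifted lists) and 4.97% of miRNA genes (2.77 times). For pseudogenes the share was 0.599% (0.527 times), with an adjusted permutation p of 0.002 for each type. Genes of these types near protein-coding gene ends were not set aside as for tRNA genes. The lncRNA and miRNA excess can therefore include islands at protein-coding genes. Families of gene names, 274 in all, were compared at the wider window of 5 kb from a gene end. No island lay there for any of 355 vomeronasal receptor genes (Vmn), where 3 counts would be a share of 0.845%. All 12 Pcdhga protocadherin genes, which share an end, were reached by 1 island.

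Within 50 kb, islands over 5 kb from any gene end (distal islands) accompanied 23 of 42 granule neuron differentiation genes (54.8%, odds ratio 7.84, adjusted exact Fisher p = 2.7e-09), among them Neurod1, Reln, Cntn2 and Mapt. They accompanied 17 of 42 granule neuron progenitor genes (odds ratio 4.39, adjusted exact Fisher p = 8.3e-05) and 16 of 41 stem and glial progenitor genes (odds ratio 4.13, adjusted exact Fisher p = 1.9e-04), among them Notch1, Sox9, Jag1 and Egfr. The Hedgehog list passed narrowly (12 of 44, adjusted exact Fisher p = 0.0497). Other lists of neural genes did not pass: regulators of other neuron types had distal islands in 9 of 46 (odds ratio 1.57, adjusted exact Fisher p = 0.401), and oligodendrocyte and astrocyte markers in 3 of 20 each (odds ratio 1.14, adjusted exact Fisher p = 0.832). Housekeeping genes had them in 8 of 39. Against housekeeping genes the adjusted exact Fisher p was 0.024 for differentiation, 0.227 for progenitor, 0.270 for stem and glial and 1 for Hedgehog genes, so only the differentiation list passed. Among length-matched random lists the differentiation list lay at percentile 99.995, progenitor and stem and glial genes at 100, and Hedgehog genes at 96.6. Of the lists that did not pass, histone genes lay at 100, cell cycle genes at 96.3, and neuronal regulators and housekeeping genes at 97.2 each. Over rotations of gene order, the two-sided permutation p was 0.445 for histone, 0.243 for cell cycle, 0.284 for neuronal regulator and 0.229 for housekeeping genes, against 0.0146 for the Hedgehog list and 0.0001 for each of the differentiation, progenitor and stem and glial lists. Members quoted here were chosen after their values were seen.

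Chromosome X held 23 islands, spread from 5205083 to 170008868, and 9 of them lay within 1 kb of a protein-coding gene end. They included islands at Ddx3x (91 reads), Stag2 (113), Ubqln2 (98) and Rps6ka3 (68), one of 87 reads at Jpx, one of 60 reads 0.372 kb from an end of Xist and one of 76 reads in Ftx, all named here after their values were seen. A low number of genes on X was argued against, since the ratio to the number expected from its genes was 0.0899 (exact 95% interval 0.057 to 0.135). A lower signal on X, as 1 copy in a male would give against a read threshold set for the whole genome, is a candidate explanation that stays open. With autosomal counts halved at fixed width, 0.427% of islands up to 6 kb kept the 1st percentile of counts at their width, but called islands span so narrow a range (95th percentile 1.62 times that count) that this test could hardly have come out otherwise and decides nothing. The sex of the animals is not given in the labels used here, so copy number and the filtering of X reads cannot be told apart.

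A set of 31 islands had over 2 times the median density (over 12.5 reads per 200 bp) and held 8.28% of all reads in islands, with 4.39% in the island at Sfi1. Of these, 9 were 400 bp wide and entered the set through their width alone, since the lowest count in the list, 27 reads, already exceeds that density; the other 22 held 8.22% of the reads. Reads from repeated sequence are a possible explanation, for which gene ends were expected to be rarer among them. Gene ends lay within 1 kb of 9 of 31 (odds ratio against the other islands 0.849, exact Fisher p = 0.848) and of 7 of the 22 (odds ratio 0.969, exact Fisher p = 1, added after seeing the data). With so few islands this comparison cannot tell repeats and binding apart. The positions were not checked against known regions of artefact signal, and input reads and sequence were not used here. These islands, the one at Sfi1 included, are therefore not shown to be Brg1 binding.

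Granule neuron progenitor genes had the highest share of any list with an island within 5 kb of a gene end, though not within 1 kb or for distal islands. Gene length was argued against, with the list at percentile 100 of length-matched random lists, as were clusters of neighbouring genes sharing islands (two-sided permutation p over rotations 0.0001, the smallest they can give). Islands at active genes in general may account for the pattern. Ribosomal protein genes, a list taken by symbol pattern whose activity was not measured, had islands in 10 of 85 (odds ratio 0.888). Without genes on both lists, 10 of 83 had them, less often than housekeeping genes (odds ratio 0.160, adjusted exact Fisher p = 2.8e-04). Against housekeeping genes the adjusted exact Fisher p was 0.155 near gene ends and 0.227 for distal islands, with 42 and 39 genes, so a lineage-specific preference and a preference for active genes cannot be told apart. Expression was not analysed here, and no biological explanation was tested.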
